A study of Mus musculus with 8 samples.

How the data were processed

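Mouse liver RNA was sequenced in 8 libraries after a 22-week regimen of fasting on alternate days. The labels place 4 libraries in a group called feeding glucose (FG, replicates 93, 94, 95 and 96) and 4 in a group called starvation glucose (SG, replicates 101, 103, 104 and 105), and the series text frames the comparison as glucose intake in the fed and the fasted state. Replicate numbers were taken from the labels and are not shared between the groups. The labels give no sex, age, strain, batch, time of collection or interval since the last glucose or food. They do not state that the 4 libraries of a group come from separate animals, although the series text counts 4 per group, so the p-values measure the spread between these libraries.

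Per the labels' protocols, total RNA was isolated with TRIzol, mRNA was enriched and fragmented, and libraries were read as 150 bp pairs on an Illumina NovaSeq instrument. Per the submitters' processing notes, fastp, HISAT2, HTSeq and DESeq2 were used with builds GRCm38 and mm10, without versions or roles; the series text adds that HISAT2 made the alignments. Whether counting used strand is not given in the sources used here, so antisense and overlapping genes cannot be told apart from their partners. The deposited values are FPKM, fragments per kilobase of gene relative to the counted total, made by the authors for 21358 genes in each of the 8 libraries. All expression columns were matched to a sample by label, and 0 columns of per-sample values were left unmatched. No raw count table was used here.

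FPKM are not counts, so the test was made on a log scale. A gene was tested when its FPKM was at least 1 in at least 4 of the 8 libraries, which kept 9867 genes. The values log2(FPKM + 1) were fitted with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, all 8 libraries, no covariates), and p-values were adjusted by Benjamini-Hochberg over all tested genes. A gene was called at an adjusted p below 0.05, two-sided, with no minimum fold. All fold changes are SG minus FG on the log2(FPKM + 1) scale, which understates changes of genes with low values, and standard errors (SE) are limma's moderated ones. Beside the limma value, an exact two-sided permutation test over the 70 assignments of 4 and 4 libraries was computed for each gene, with a smallest possible p of 0.0286.

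Before the data were examined, 54 gene lists were fixed for pathways, regulators, liver zones and other cell types, together with the test, the threshold, the alternative settings and the rule for genes named in the text. Of 817 list memberships, 805 were found in the table through symbols, synonyms or gene IDs, and 649 were tested; the others are not analysed here. Lists with at least 3 tested members, 51 in all, were compared with the remaining genes by limma's camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the data and fry, which asks whether a list's genes move one way on balance, were run beside it. Named genes were the 10 with the largest rise and the 10 with the largest fall among called genes with an official symbol, a mean of at least 2 FPKM in the higher group and non-overlapping groups. To these were added up to 4 members with the smallest p of each list past the threshold, up to 2 called members of each other list, and 20 genes fixed beforehand whatever their values. Any other gene named was chosen after its values were seen. The values of some genes that this rule names are not reported here.

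Depth was recovered from the steps of the FPKM values. Each gene's values were whole multiples of what 1 fragment is worth, and a whole count was found for 100% of the 21358 genes within a tolerance of 0.02 fragments. The absolute total was fixed by 236 genes whose recovered length matched the union of their annotated exons in GENCODE vM21. Sums of recovered counts differed from the totals by at most 0.0312%. In a simulated table, 99.8% of genes with a mean of 20 or more fragments were recovered exactly. Totals were 36545128 to 41977438 fragments per library. Values of tested genes between 0.9 and 1.1 FPKM rested on a median of 167 fragments (quartiles 101 and 273). Recovered counts entered the main test in no way; they served library-level shares and added alternatives (limma voom, and thinning every library to 36545128 fragments).

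Gene positions are those of the RefSeq table for GRCm38.p6, the same build, in which 20804 of the 21358 gene IDs were found. Alternatives fixed at that stage covered the pseudocount (0.1), the filter (none, or a mean of at least 5 FPKM), scaling between libraries (median-ratio, trimmed mean, quantile), rescaling without the 13 mitochondrially encoded protein genes and the 10 most abundant genes, the variance model, library weights, the thresholds, and leaving out each library in turn. A count test foreseen for that case on raw counts was not run, because the unit turned out to be FPKM. Reactome terms carried in the deposited table were tested with camera after the data had been seen (873 terms with 10 or more tested genes). The test was tried on simulated values for the 9867 genes with the residual spread of these libraries: 80% of genes changed 2 fold and 55% of those changed 1.5 fold were called, and 1.46% of the calls were unchanged genes. Genes were simulated as independent of each other and without a shift common to all, so these rates may not carry over to the real libraries. Recovery, shares and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

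FPKM are shares of a total, so a gain in some genes lowers the values of all others. The total contains no external standard here, and the scaling alternatives assume that most genes did not change. Families of near-identical genes share reads that HTSeq-type counting can drop or split, and the values of Mup, Cyp2b, Cyp2a, Cyp4a, Gsta, Gstm, Selenbp and Serpina1 genes are uncertain for that reason.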

Results

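Hepatic gene expression was measured by RNA sequencing in 4 FG and 4 SG mouse libraries after the 22-week alternate-day fasting regimen. FG denotes glucose given in the feeding state and SG glucose given in the starvation state, as far as the labels say. The libraries held 38253764 to 41977438 counted fragments in FG and 36545128 to 39214619 in SG, and the group means did not differ past the threshold (n = 4 each, exact two-sided permutation p = 0.171). The first principal component of the tested genes carried 45.4% of the variance and separated all FG libraries (scores -31.4 to -10.2) from all SG libraries (7.64 to 28.5). SG 101 lay closest to the FG libraries on that axis. Correlations of log2(FPKM + 1) between libraries had a median of 0.977 within groups and 0.962 between groups.

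The comparison of SG with FG asks how the hepatic transcriptome differed with the metabolic state in which glucose was taken. The labels give no hour of collection or interval since the last food or glucose. Effects of a difference in either between the groups cannot be told apart from those of that state. In SG, 17 of 20 tested genes of fatty acid synthesis fell, as did 8 of 13 of glycolysis and 6 of 7 of fructose use. So did 5 of 8 of the pentose phosphate pathway and NADPH supply. Of the genes of amino acid breakdown and the urea cycle 11 of 27 rose, and of those of bile acid synthesis and transport 6 of 19. These lists passed camera with a preset correlation and none did with an estimated one (adjusted p = 0.286 for fatty acid synthesis and adjusted p = 0.396 for the others). Pklr, the liver pyruvate kinase, fell from 425 ± 45.5 to 47.1 ± 25.2 FPKM (SD, n = 4 each), and Scd1, the fatty acyl desaturase, from 4719 ± 417 to 882 ± 297 FPKM. Bhmt, which remethylates homocysteine with betaine, rose from 195 ± 99.6 to 2635 ± 485 FPKM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 20.2 ± 16.3 to 112 ± 29.4 FPKM.

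Of 9867 genes tested with limma, 1912 (19.4%) were called, 368 higher and 1544 lower in SG, so that 80.8% of the calls were lower. The median log2 fold change of all tested genes was -0.135. After median-ratio scaling, which moved that median to 0.006, 1044 genes were called, 545 higher and 499 lower. Changes below are given on the deposited FPKM scale, and a list's median is also given relative to the median of all tested genes. Among the called genes, 95 were at least 2-fold higher and 137 at least 2-fold lower. In 1780 of the called genes the 4 values of one group all lay above the 4 of the other. Among all tested genes such separation was seen for 26.1%, where 2.86% is the share given by chance. Without FG 93 the count of calls was 834, without FG 95 1102, without SG 103 1087, and without SG 104 or SG 105 1036 each.

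**Figure D1:**
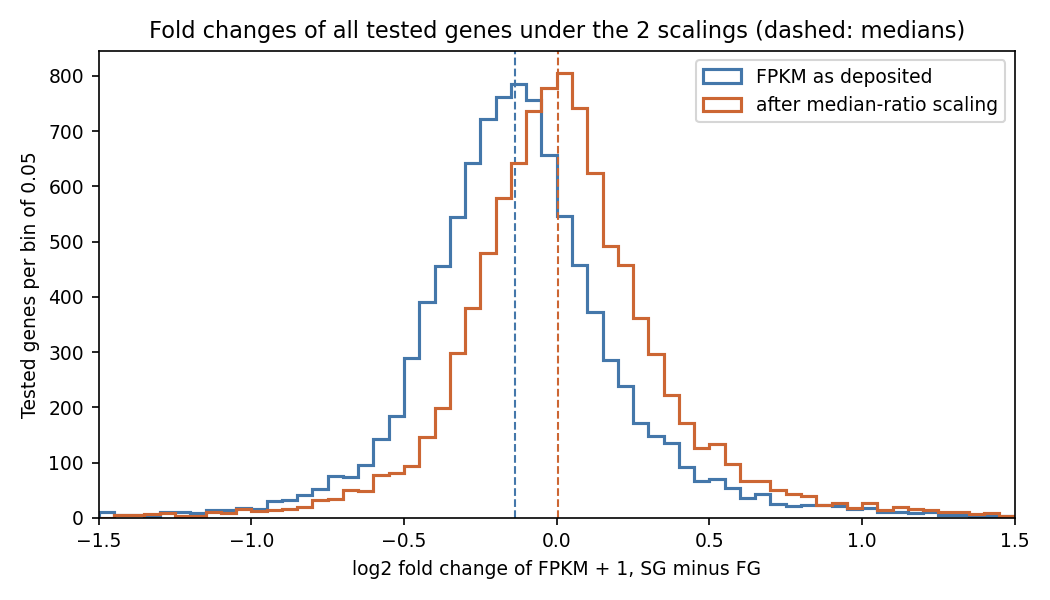
Histogram of the log2 fold change of FPKM + 1 (SG minus FG) over the 9867 tested genes, in bins of 0.05, as deposited and after median-ratio scaling; dashed lines mark the medians of -0.135 and 0.006, and 99 genes beyond ±1.5 under either scaling are not drawn. On the deposited scale the distribution is centred below 0.

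The 10 genes with the largest falls comprised 6 of lipogenesis and its supply of substrate (Pklr, Me1, Elovl6, Fasn, Acly and Scd1) and also Cyp2b9, Rgs16, Gstm3 and Serpina7. Elovl6, an elongase of long-chain fatty acids, had a log2 fold change of -2.87 (SE 0.152, adjusted p = 3.24e-05). Its gene (NCBI gene 170439) spans positions 129532386 to 129638495 of chromosome 3 in GRCm38. Cyp2b9, a cytochrome P450 with higher expression in female than in male mouse liver, fell from 53.4 ± 35 to 0.137 ± 0.146 FPKM (log2 fold change -5.31, SE 0.446, adjusted p = 0.000433). It lies on chromosome 7 between 26173350 and 26210661, within a cluster of related Cyp2 genes, and its reads are hard to separate from theirs. Rgs16, a regulator of G protein signalling, fell by 3.59 on the log2 scale (SE 0.656, adjusted p = 0.0092), and Serpina7, thyroxine-binding globulin, fell by 2.72 (SE 0.515, adjusted p = 0.0104). Gstm3, a glutathione transferase with close paralogs, fell from 278 ± 226 to 32.7 ± 22.9 FPKM (adjusted p = 0.0223), and lost the call in 5 of the 8 fits that left out 1 library (without FG 93, FG 95, SG 103, SG 104 or SG 105, highest adjusted p = 0.0603).

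The 10 genes with the largest rises were Selenbp2, Mup7, Bhmt, Serpina1e, Enho, Cyp7a1, Asns, Igfbp1, Elovl3 and Urml. Enho, which encodes the secreted peptide adropin, rose from 0.569 ± 0.0922 to 10.1 ± 1.83 FPKM (log2 fold change 2.81, SE 0.126, adjusted p = 1.08e-05), the smallest adjusted p among these 10 genes. It lies on chromosome 4 from 41638144 to 41640302. Igfbp1, an insulin-repressed binding protein of IGF, rose from 20.8 ± 7.12 to 119 ± 81.9 FPKM (adjusted p = 0.0151). Asns, asparagine synthetase, rose from 3.20 ± 3.25 to 20 ± 7.35 FPKM (adjusted p = 0.00875). Selenbp2, Serpina1e and Mup7, which are higher in male than in female mouse liver, rose by 4.97 (SE 0.438), 3.56 (SE 0.365) and 4.29 (SE 1.02) on the log2 scale. Each of these 3 genes has near-identical paralogs, so its share of reads is uncertain. Mup7 lost the call without FG 93, SG 103 or SG 104 (highest adjusted p = 0.0674).

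**Figure D2:**
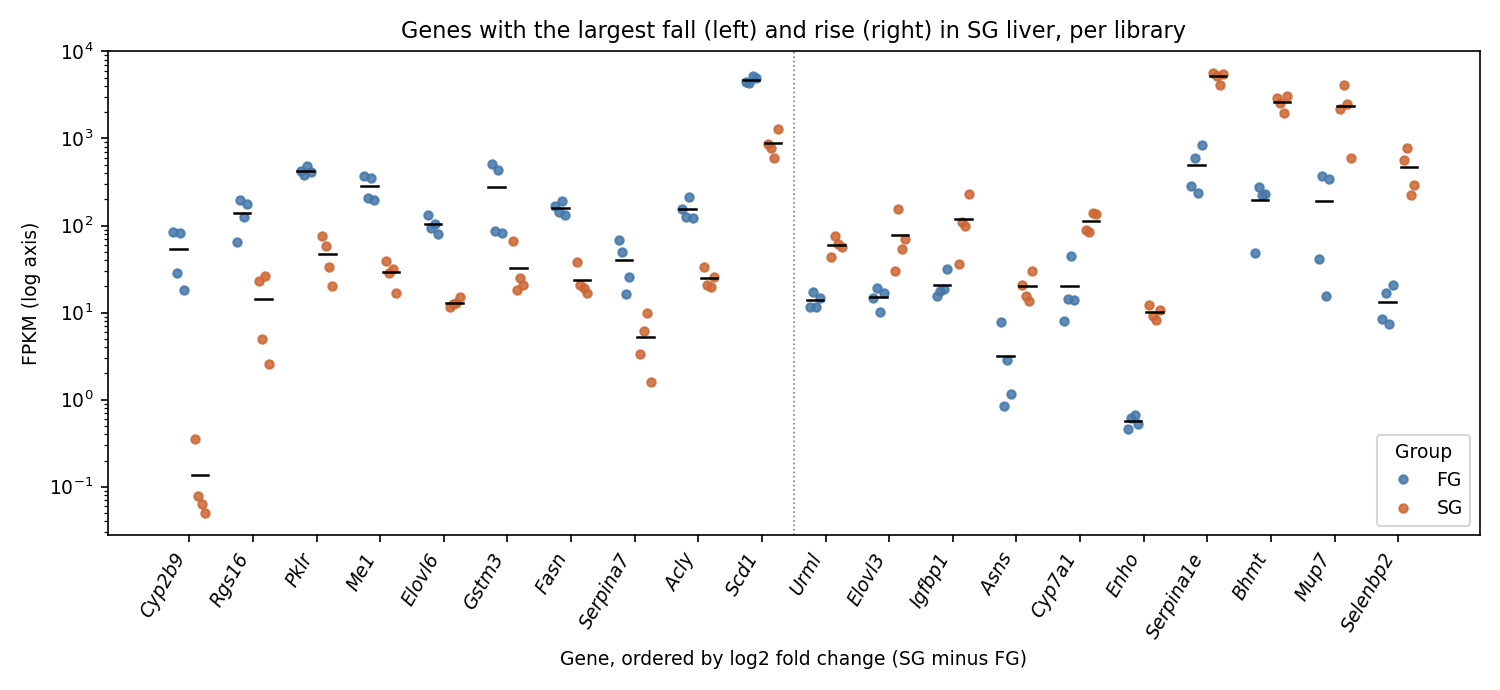
FPKM on a log axis for the 10 genes with the largest fall (left) and the 10 with the largest rise (right) in SG, 1 point per library and a bar at each group mean (n = 4 per group). In each gene the 4 values of one group lie above the 4 of the other, as in Enho, where FG averages 0.569 and SG 10.1 FPKM.

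By median, de novo fatty acid synthesis was the list with the largest fall. Of its 20 tested members 17 fell and none rose, and 18 fell when adjusted over the list alone. After median-ratio scaling 14 fell and none rose. The median log2 fold change was -1.70 (-1.57 relative to all tested genes). Fasn, fatty acid synthase, fell from 160 ± 26.5 to 23.7 ± 9.67 FPKM, Acaca, acetyl-CoA carboxylase, from 43.2 ± 10.7 to 8.21 ± 1.33 FPKM, and Acly, ATP citrate lyase, from 154 ± 41.6 to 24.7 ± 6.33 FPKM (adjusted p = 0.000433 in each). Srebf1, a transcription factor of lipogenesis, fell by 1.58 on the log2 scale (SE 0.303, adjusted p = 0.011). Mlxipl, which encodes the carbohydrate response factor ChREBP, was at 64.0 ± 21.3 and 41.2 ± 11.3 FPKM and did not pass (adjusted p = 0.157; it passed without FG 95). Camera gave an adjusted p of 4.9e-12 for the list with the preset correlation and adjusted p = 0.286 with an estimated correlation. Of 51 lists tested, 21 passed with the preset correlation, 14 higher and 7 lower, and 0 with an estimated one, whose p follows each preset p. By fry, which asks whether a list's genes move one way on balance, 17 of the 51 lists passed, 12 of them among the 21. Not past fry were bile acids (adjusted p = 0.117), male-biased genes (0.13), fatty acid oxidation (0.258), gluconeogenesis (0.258) and cholesterol biosynthesis (0.524). Nor were mitochondrially encoded genes (0.197), glucocorticoid targets (0.403), ribosomal proteins (0.461) and pericentral genes (0.461). Fry measures against 0 and not against the other genes, so the median of -0.135 over all tested genes can favour lists that fell.

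In glycolysis, 8 of 13 tested members fell (10 fell and 1 rose adjusted over the list alone, 6 fell and 1 rose after median-ratio scaling), with a median of -0.57, or -0.43 relative to all genes (adjusted p = 0.00167, and adjusted p = 0.396 with an estimated correlation). Gpi1, glucose phosphate isomerase, fell from 198 ± 43.8 to 56.8 ± 8.82 FPKM, and Pdha1, a subunit of pyruvate dehydrogenase, from 82.4 ± 10.5 to 47.0 ± 7.36 FPKM. In fructose metabolism, 6 of 7 members fell, and 7 fell adjusted over the list alone (median -0.60, adjusted p = 0.000328, and adjusted p = 0.396 with an estimated correlation). Khk, ketohexokinase, fell from 423 ± 33.2 to 154 ± 34.3 FPKM, and Tkfc, triokinase, from 334 ± 46.2 to 73.0 ± 22.9 FPKM. After median-ratio scaling 3 of these 7 members fell. In the pentose phosphate and NADPH list, 5 of 8 fell, and 7 adjusted over the list alone (median -1.07, adjusted p = 0.00107, and adjusted p = 0.396 with an estimated correlation). Me1, malic enzyme, fell from 283 ± 93.1 to 28.9 ± 9.33 FPKM and Pgd, phosphogluconate dehydrogenase, from 46.3 ± 14.2 to 14.3 ± 4.13 FPKM. In glycogen metabolism 4 of 14 fell, 5 adjusted over the list alone, among them Gbe1, the branching enzyme, by 1.42 and Ugp2, which makes UDP-glucose, by 1.46 on the log2 scale. The list itself did not pass (adjusted p = 0.183, and adjusted p = 0.464 with an estimated correlation). It passed with no filter on low values (0.0288), with a mean of at least 5 FPKM (0.0448) and by fry (0.00202).

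Amino acid catabolism and the urea cycle was the list with the smallest camera p among those higher in SG. Of 27 tested members 11 rose and none fell, 14 rose adjusted over the list alone, and the median was 0.67 (0.80 relative to all genes; adjusted p = 2.58e-15, and adjusted p = 0.396 with an estimated correlation). Cth, cystathionine gamma-lyase, rose from 79.6 ± 21.3 to 303 ± 110 FPKM, Gpt, alanine aminotransferase, from 116 ± 26.1 to 254 ± 55.8 FPKM, and Oat, ornithine aminotransferase, from 204 ± 35.5 to 385 ± 68.6 FPKM. Periportal hepatocyte genes, some of which also belong to that list, rose in 7 of 14 members and fell in none (8 and 1 adjusted over the list alone; median 0.79, adjusted p = 1.09e-06, and adjusted p = 0.381 with an estimated correlation). Ass1, argininosuccinate synthase, rose from 1144 ± 324 to 2797 ± 971 FPKM and Gldc, glycine decarboxylase, from 19.1 ± 3.05 to 42.4 ± 13.1 FPKM. Cps1, carbamoyl phosphate synthetase, rose from 706 ± 189 to 1324 ± 256 FPKM (adjusted p = 0.0193; 0.0517 without SG 105). Pericentral genes had a median of -0.007 (0.16 after median-ratio scaling) beside a mean of 0.22 and a camera direction towards SG (adjusted p = 0.0268, and adjusted p = 0.58 with an estimated correlation). Their 3 rises of 13 members, the same number adjusted over the list alone, were Cyp7a1, Oat and Cyp27a1 (lost without FG 93 or SG 104, highest adjusted p = 0.0536), and Glul, glutamine synthetase, was at 505 ± 45.1 and 366 ± 103 FPKM (adjusted p = 0.11). The pericentral call was lost after median-ratio scaling (adjusted p = 0.0944), trimmed-mean scaling (0.0928) and quantile normalization (0.273), with no filter (0.126), without SG 101 (0.151) and without SG 104 (0.0615).

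**Figure D3:**
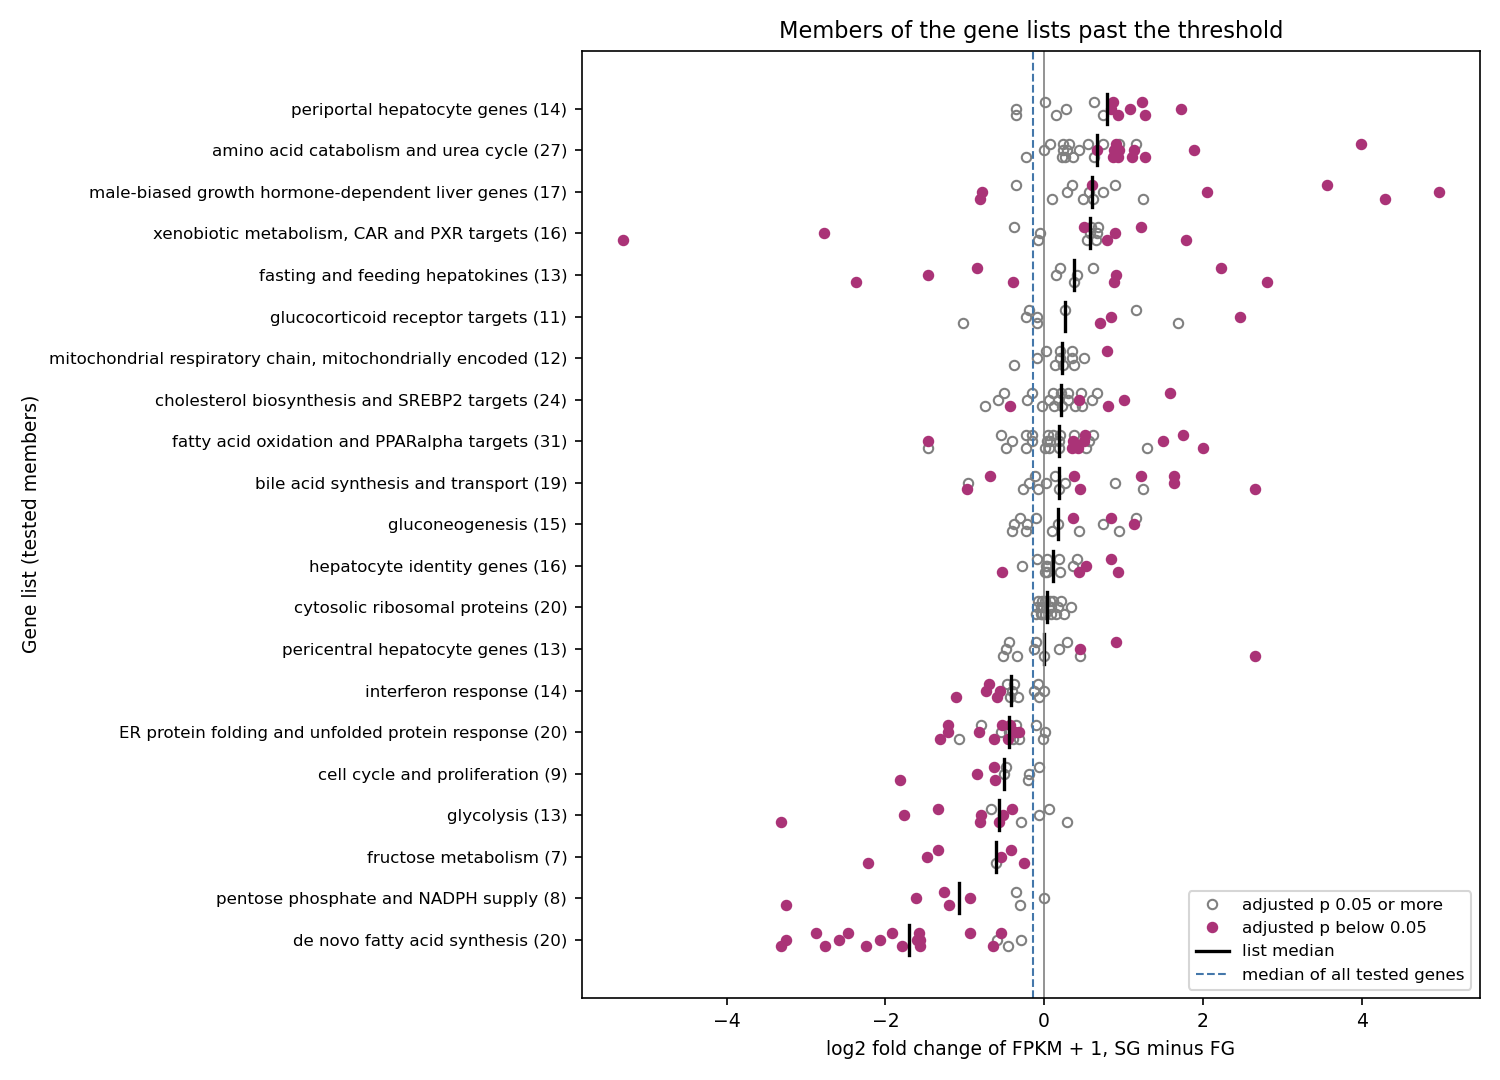
Log2 fold change of FPKM + 1 (SG minus FG) of the tested members of the 21 gene lists past the threshold, 1 point per gene, filled where the gene's adjusted p is below 0.05; black bars mark list medians and the dashed line the median of all tested genes at -0.135. The medians run from -1.70 for de novo fatty acid synthesis to 0.79 for periportal genes.

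In bile acid synthesis and transport, 6 of 19 tested members rose and 2 fell (8 and 3 adjusted over the list alone; median 0.18, adjusted p = 0.000328, and adjusted p = 0.396 with an estimated correlation). Beside Cyp7a1, Cyp8b1, the 12-alpha hydroxylase of cholic acid synthesis, rose from 79.8 ± 24.1 to 245 ± 34.5 FPKM, and Akr1d1, the 5-beta-reductase, from 19.1 ± 4.99 to 44.9 ± 4.00 FPKM. Of the transporters in the list, Abcb11, the bile salt export pump, fell from 101 ± 11.2 to 51.4 ± 7.63 FPKM, and Slc10a1, the uptake transporter NTCP, from 507 ± 46.5 to 315 ± 34.9 FPKM. Slco1a4, an organic anion transporter named after its values were seen, rose from 9.66 ± 2.16 to 33.6 ± 13.8 FPKM (adjusted p = 0.00743). Cholesterol biosynthesis rose in 4 of 24 members and fell in 1, in the same numbers adjusted over the list alone (median 0.22, adjusted p = 0.00041, and adjusted p = 0.592 with an estimated correlation; 0.0583 without SG 101). Msmo1, a sterol methyl oxidase, rose from 21.5 ± 9.76 to 66.1 ± 26.0 FPKM.

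Across the lists of fatty acid oxidation, ketogenesis, gluconeogenesis and hepatokines, called members lay in both directions. In fatty acid oxidation and PPAR-alpha targets, 8 of 31 members rose and 1 fell (9 and 3 adjusted over the list alone; median 0.19, adjusted p = 2.87e-05, and adjusted p = 0.43 with an estimated correlation). Acot1, an acyl-CoA thioesterase, rose from 13.6 ± 1.87 to 50 ± 17.2 FPKM, and Cpt2, carnitine palmitoyltransferase 2, from 56.6 ± 1.6 to 76.6 ± 4.40 FPKM. Fgf21, a hepatokine induced by PPAR-alpha, fell from 6.28 ± 2.54 to 1.69 ± 1.02 FPKM (log2 fold change -1.47, SE 0.321, adjusted p = 0.0168). Cpt1a (log2 fold change 0.35, adjusted p = 0.0398) and Pdk4 (1.49, adjusted p = 0.0498) rose, and each lost the call in 6 of the 8 fits without 1 library (highest adjusted p = 0.113 and 0.121), Pdk4 also after median-ratio scaling (adjusted p = 0.0507). Cyp4a14, a microsomal fatty acid hydroxylase, had a log2 fold change of -0.49 (adjusted p = 0.624). Of its paralogs in the list, named after their values were seen, Cyp4a10 rose by 2.01 on the log2 scale (limma adjusted p = 0.0315). Cyp4a31 had a log2 fold change of 1.30 and did not pass (limma adjusted p = 0.0801). In ketogenesis 1 of 5 members fell, also adjusted over the list alone: Bdh1, the ketone body dehydrogenase, from 95.9 ± 9.55 to 51.1 ± 13.1 FPKM. In gluconeogenesis, 3 of 15 rose and none fell, 4 adjusted over the list alone (median 0.18, adjusted p = 0.00428, and adjusted p = 0.426 with an estimated correlation; 0.273 after quantile normalization). Pck1, the cytosolic PEP carboxykinase, rose from 815 ± 215 to 1452 ± 300 FPKM (adjusted p = 0.023), a call lost without FG 93, FG 95, SG 104 or SG 105 (highest adjusted p = 0.0657). G6pc, glucose-6-phosphatase, was at 252 ± 161 and 219 ± 105 FPKM (adjusted p = 0.905). Irs2 was at 3.35 ± 1.92 and 5.38 ± 1.74 FPKM (adjusted p = 0.199), and Ppargc1a, at 0.682 ± 0.125 and 1.59 ± 0.876 FPKM, lay below the filter. Among hepatokines 4 of 13 members rose and 4 fell (8 and 4 adjusted over the list alone, 7 and 2 after median-ratio scaling; median 0.38, adjusted p = 0.00221, and adjusted p = 0.286 with an estimated correlation; 0.191 after quantile normalization). Angptl8, a feeding-induced inhibitor of lipoprotein lipase, fell from 32.2 ± 11.8 to 5.15 ± 0.953 FPKM.

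Some members of the lists for protein folding in the endoplasmic reticulum, interferon response and cell cycle fell in SG. In the folding list, 10 of 20 members fell and none rose, 16 adjusted over the list alone, and 5 after median-ratio scaling (median -0.45, or -0.31 relative to all genes; adjusted p = 0.000328, and adjusted p = 0.396 with an estimated correlation). Xbp1, a transcription factor of the unfolded protein response, fell from 105 ± 18.6 to 45.5 ± 12.6 FPKM, Hspa5, the chaperone BiP, from 181 ± 15.6 to 117 ± 11.3 FPKM, and Hyou1, its cochaperone, from 28.8 ± 6.74 to 12.0 ± 3.45 FPKM. Interferon response genes fell in 5 of 14 members, also adjusted over the list alone, and in 3 after median-ratio scaling (median -0.41, adjusted p = 0.038, and adjusted p = 0.508 with an estimated correlation). Usp18, a negative regulator of interferon signalling, fell from 7.26 ± 1.26 to 2.86 ± 0.754 FPKM. The interferon call was lost without FG 94, FG 95, SG 104 or SG 105 (adjusted p = 0.0569, 0.0639, 0.0892 and 0.0594), and with a filter at a mean of 5 FPKM (0.083). Cell cycle genes fell in 4 of 9 tested members, 5 adjusted over the list alone, and in 2 after median-ratio scaling (median -0.51, adjusted p = 0.029, and adjusted p = 0.509 with an estimated correlation; 0.0639 without FG 95, 0.0708 without SG 104 and 0.866 with no filter on low values). Ccnd1, cyclin D1, fell from 17.4 ± 6.46 to 4.09 ± 1.07 FPKM.

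Among xenobiotic metabolism genes 5 of 16 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.58 beside a mean of 0.02, adjusted p = 4.65e-05, and adjusted p = 0.142 with an estimated correlation). Por, the reductase that supplies electrons to cytochromes P450, rose from 211 ± 18.5 to 398 ± 72.0 FPKM, and Cyp2c54 from 96.4 ± 23.8 to 224 ± 35.3 FPKM. The members that fell were Cyp2b9 and Gstm3. Male-biased growth hormone-dependent genes rose in 5 of 17 members and fell in 2 (7 and 2 adjusted over the list alone; median 0.60, adjusted p = 3.57e-06, and adjusted p = 0.396 with an estimated correlation); after median-ratio scaling 6 rose and none fell. Elovl3, an elongase of very long chain fatty acids, rose from 15.3 ± 3.84 to 76.8 ± 53.5 FPKM. In FG, Mup7 was at 41.5, 372, 15.4 and 346 FPKM in FG 93, 94, 95 and 96. Of 6 tested female-biased genes 1 fell, Cyp2b9, and 2 adjusted over the list alone. The list did not pass (adjusted p = 0.384).

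Mitochondrially encoded genes of the respiratory chain had a median of 0.22, with 1 rise (ND6, lost in 7 of the 8 fits without 1 library, highest adjusted p = 0.113) among 12 members, 0 adjusted over the list alone and 2 after median-ratio scaling (adjusted p = 0.00123, and adjusted p = 0.396 with an estimated correlation; 0.161 after quantile normalization). Their share of all fragments was 5.82 ± 0.543% in FG and 6.51 ± 0.316% in SG (SD, n = 4 each, exact permutation p = 0.0571, adjusted 0.114 over 6 library measures). Cytosolic ribosomal protein genes had a median of 0.04 and 0 calls among 20 members, also adjusted over the list alone, and 3 rises after median-ratio scaling (adjusted p = 0.00428, and adjusted p = 0.508 with an estimated correlation; 0.0723 without FG 94, 0.0645 without SG 101 and 0.592 after quantile normalization). Hepatocyte identity genes rose in 4 of 16 members and fell in 1, Cebpa (adjusted p = 0.0507 after median-ratio scaling), or in 5 and 1 adjusted over the list alone and 6 and 0 after median-ratio scaling (median 0.11, adjusted p = 0.000759, and adjusted p = 0.286 with an estimated correlation; 0.195 after quantile normalization). Serpina3k, a secreted serpin, rose from 4255 ± 905 to 7538 ± 1188 FPKM. Glucocorticoid receptor targets rose in 3 of 11 (4 and 1 fall adjusted over the list alone; median 0.26, adjusted p = 0.00731, and adjusted p = 0.508 with an estimated correlation), and that call was lost after median-ratio scaling (0.066), trimmed-mean scaling (0.0654) and quantile normalization (0.0872), without FG 93 (0.0781) and without SG 105 (0.103).

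No tested list of markers of other cell types passed camera with all 8 libraries and the main settings. Lymphocyte, neutrophil and mesothelial markers had 0, 1 and 2 tested members, so these lists were not tested. By fry, only cholangiocyte markers passed among the lists of other cell types (adjusted p = 0.0119). Of 16 tested macrophage markers 1 fell, Cd9, which hepatocytes also express, from 26.2 ± 6.98 to 5.71 ± 0.875 FPKM (list median -0.18, adjusted p = 0.951). Sinusoidal endothelial markers fell in 2 of 12, Clec4g and Fcgr2b (median -0.22, adjusted p = 0.605). Neither passed after median-ratio scaling (adjusted p = 0.0542 and 0.369), Clec4g lost the call without FG 93 (0.0514), and Fcgr2b in each of the 8 fits without 1 library (highest adjusted p = 0.124). Stellate cell markers fell in 0 of 11 (median 0.002, adjusted p = 0.202; 0.0457 without FG 93), and cholangiocyte markers in 2 of 4, Krt23 and Spp1, the latter lost after median-ratio scaling (adjusted p = 0.0744) and in 5 of the 8 fits without 1 library, highest adjusted p = 0.0619 (median -0.66, adjusted p = 0.241). Nearest to the threshold were gallbladder and intestinal epithelium markers, of which 2 of 3 rose, Tff3 and Lgals4 (median 1.16, adjusted p = 0.0578), and adipocyte markers, of which 1 of 4 rose, Cdo1, which liver also expresses (median 0.26, adjusted p = 0.0578). The first list passed without FG 96 (0.032), without SG 101 (0.0391) and with a pseudocount of 0.1 (0.0498), and the second without FG 93 (0.0247), without SG 103 (0.0295) and with library weights (0.0462). Both were at adjusted p = 0.396 with an estimated correlation. Tff3 lost the call without FG 93, FG 94 or FG 95 (highest adjusted p = 0.0858), and Lgals4 and Cdo1 in 7 of the 8 fits without 1 library (0.118 and 0.108). These counts were the same adjusted over the list alone. Acute phase genes rose in 1 and fell in 2 of 22, also adjusted over the list alone, and rose in 2 and fell in 0 after median-ratio scaling (median 0.03, mean -0.02, adjusted p = 0.0957 towards SG; 0.0202 without FG 95 and 0.00494 without SG 104). In the clock list 2 of 16 members rose and 3 fell (4 and 4 adjusted over the list alone; median -0.20 beside a camera direction towards SG, adjusted p = 0.479). Nr1d1, the nuclear receptor REV-ERB-alpha, fell from 20.7 ± 2.79 to 6.22 ± 3.46 FPKM, and Nfil3, a repressor of D-box genes, rose from 1.80 ± 0.536 to 5.33 ± 1.38 FPKM.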

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

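Tests chosen only after the result was seen were those of the daily cycle, of female RNA, of thinning and of shared reads among paralogs; the bounds of the daily cycle and paralog tests were also reworded after their values had been seen.

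In 282 checks of 4 libraries of one group for a single value far from the other 3, 14 values stood out, where chance gives about 14.1. In SG 101 these were Akr1d1 at 38.93 FPKM (others 46.68 to 47.08), Cyp2b9 at 0.3552 (0.0496 to 0.07886), Irs2 at 2.8 (5.99 to 6.631), Pdk4 at 2.548 (9.309 to 10.84), Pgd at 20.49 (11.84 to 12.63) and S100a9 at 0.438 (0.94 to 1.035). In SG 105 they were Cyp2c54 at 171.1 FPKM (236.8 to 247.2) and Pdk1 at 14.58 (18.95 to 19.26). In FG 93 they were Bhmt at 48.91 FPKM (226.9 to 274.6), Gpt2 at 47.99 (64.88 to 66.72) and Pdk4 at 5.549 (1.114 to 1.511). In FG 95 Pdk1 stood at 34.28 FPKM (29.17 to 29.97) and Rpl23 at 107.8 (130.6 to 135.1), and in FG 96 Cebpa at 109 (133.7 to 137.2).

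The count of 1912 called genes was reached by 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, and the highest other split gave 4. Only 35 splits exist, and every other split mixes libraries of both groups, which adds the group difference to their spread. The real split stands out from them, but the test cannot exclude chance.

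The first pattern is the excess of lower over higher calls, 1544 against 368. A few abundant genes taking more of the total were argued against, since rescaling without the mitochondrially encoded and the 10 most abundant genes left the median log2 fold change at -0.119. For lower depth in SG, the bound set beforehand was met: genes with a mean of at least 50 FPKM had a median of -0.00463. That value does not single out depth, because a shift of share towards abundant genes gives it too. Thinning every library to 36545128 fragments made depth equal and left the median at -0.136, with 366 calls higher and 1532 lower. An effect of the number of fragments counted would have been removed, so these values argue against lower depth. Still open is whether the less abundant genes fell or whether gains spread over many abundant genes reduced their share. Both may leave the same FPKM. The 1059 genes at or above 50 FPKM held 70 ± 1.52% of fragments in FG and 72.5 ± 1.07% in SG (SD, n = 4 each, exact permutation p = 0.0286, adjusted 0.114).

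The second pattern is the lower level of Dbp, Nr1d1 and Rgs16 in SG. Collection at another phase of the daily cycle was examined with an index of Arntl, Npas2 and Clock against Dbp, Nr1d1, Nr1d2, Tef and Per3, which lay 1.91 log2 units higher in SG (exact two-sided permutation p = 0.0571). That value decides nothing, since the index holds Dbp and Nr1d1 themselves, and Arntl and Npas2 were below 1 FPKM in every library. Arntl and Npas2 lay below the filter and were not tested by limma. Of the remaining members none passed the limma threshold. The log2 fold change was 0.91 for Clock, -0.22 for Nr1d2, -0.41 for Tef and -0.06 for Per3 (limma adjusted p = 0.0683, 0.552, 0.0822 and 0.806). Every SG library lay above every FG library for Arntl and below for Tef (unadjusted exact two-sided permutation p = 0.0286 each). The groups overlapped for Npas2 and for Clock, Nr1d2 and Per3 (unadjusted exact two-sided permutation p = 0.114, 0.457 and 0.686 for these 3 genes). An effect of glucose timing on these genes and a different hour of collection cannot be told apart, since the labels give no hour.

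The third pattern is the rise of 5 of 17 male-biased genes, among them Selenbp2, Serpina1e and Mup7, and the fall of Cyp2b9 in SG; 2 of the 17 fell, and the list had an adjusted p = 0.396 with an estimated correlation and 0.13 by fry. The FG libraries differed among themselves, which was not tested. In FG 93, 94, 95 and 96, Cyp2b9 was at 84.1, 28.1, 82.8 and 18.4 FPKM, and Serpina1e at 286, 604, 238 and 849 FPKM. Female RNA among the FG libraries was argued against by Xist, at most 0.00572 FPKM there. For Serpina1e, reads moving from other family members were argued against. Its 5 others changed by 0.397 of its gain (less 2 SE, 0.109), where at least -0.5 was needed. For Selenbp2 the value was -0.13 (less 2 SE, -0.285). Its 1 other member averaged 15710 fragments in FG, against 29970 for Selenbp2 in SG. The bound could thus hardly be met and decides little, although all those reads could not supply the whole rise. Shared reads that counting dropped were not examined for either gene. For Mup7 the other Mup genes changed by 0.971 of its gain, with a lower bound of -1.07, which leaves such sharing open. For Selenbp2 and Serpina1e an effect of the state in which glucose was taken may remain as a hypothesis, and was not tested further.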

How the results depend on the processing

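Fits with voom and with thinned libraries were chosen only after the data had been seen. No paired analysis was possible because the groups share no replicate numbers, and the count test foreseen for raw counts was not run. Of 1912 calls (368 higher, 1544 lower), no call changed sign under any setting. Median-ratio scaling gave 1044 (545 higher, 499 lower) and kept 861 of the calls, trimmed-mean scaling 1050 (548 and 502), quantile normalization 1078 (462 and 616), and voom with median-ratio factors 1033 (538 and 495). These scalings moved the median of all genes from -0.135 to near 0, which by construction turns small falls into no change. No filter gave 1133 (219 and 914), with more genes tested. A mean of at least 5 FPKM gave 1378 (299 and 1079), with fewer genes tested. Under that filter the exact permutation test of single genes had 1665 genes at the smallest p, against 2580. Library weights gave 572 higher genes; the cause was not tested. Other thresholds gave 257 (110 and 147) at an unadjusted p below 0.05 with a log2 fold of at least 1, 232 (95 and 137) at the adjusted threshold with that fold, and 2922 (548 and 2374) at an adjusted p below 0.1. Leaving out 1 library gave 834 (without FG 93) to 2363 (without SG 101) calls, 181 to 467 higher and 653 to 1896 lower. The pseudocount, variance model, voom without scaling factors and thinning kept each count within 1.5 times.

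With an estimated correlation 0 of the 21 lists passed, and 12 of them passed by fry; leaving out 1 library gave 19 to 24. Over 51 lists and 22 settings, 1039 results stayed on their side of the threshold, 50 lost it, 27 gained it, and 0 called lists changed direction. Over 134 named genes and 21 settings the numbers were 2431, 329, 31 and 0; 78 of the 117 called named genes passed in each fit without 1 library, and 94 after median-ratio scaling. Values of tested genes near 1 FPKM rested on a median of 167 fragments.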

Other observations

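The Reactome terms, and all genes named in the next paragraph, were chosen after the data had been seen; the test of ChREBP was set beforehand.

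In COPI-mediated anterograde transport 31 of 73 tested genes fell and none rose (median -0.316, camera adjusted p = 6.92e-05, and adjusted p = 0.936 with an estimated correlation), and after median-ratio scaling 8 fell. Arcn1, a coatomer subunit, fell from 63.2 ± 4.15 to 41.2 ± 4.58 FPKM (SD, n = 4 each), and stayed past the threshold after that scaling (adjusted p = 0.0153), while Copa and Copb1 did not (0.092 and 0.0734). In peroxisomal lipid metabolism 6 of 24 rose and none fell (adjusted p = 0.000391, and adjusted p = 0.936 with an estimated correlation). In all, 77 of 873 terms passed with the preset correlation and 0 with an estimated one. Among single genes outside the naming rule, Lepr, the leptin receptor, fell from 12.9 ± 3.83 to 1.83 ± 1.19 FPKM (limma adjusted p = 0.00319), Aqp8, an aquaporin, from 64.9 ± 25.3 to 11.8 ± 6.81 (0.00615) and Atf5, a stress-related transcription factor, from 137 ± 41.5 to 41.3 ± 12.9 (0.00389). Agxt, a peroxisomal aminotransferase, rose from 39.7 ± 18.7 to 133 ± 27 FPKM (0.00838).

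Among ATF4 targets 6 of 13 fell and 1 rose (8 and 1 adjusted over the list alone, 1 and 1 after median-ratio scaling; adjusted p = 0.127, 0.0277 after median-ratio scaling, and adjusted p = 0.675 with an estimated correlation); the rise was Asns. Among NRF2 targets 6 of 13 fell and 2 rose (9 and 2 adjusted over the list alone, 4 and 0 after median-ratio scaling; adjusted p = 0.204, 0.03 after median-ratio scaling, and adjusted p = 0.75 with an estimated correlation).

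Cyp2a4, a female-biased gene, was at 219, 5.74, 239 and 1.30 FPKM in FG 93, 94, 95 and 96 and at 1.01 or less in SG, and Gstm3 at 507, 86.9, 437 and 82.4 FPKM in the same FG libraries. Ddx3y, a Y-linked gene, was at 0.904 FPKM in FG 95 and between 4.00 and 19.0 in the other 7 libraries, and Kdm5d, also Y-linked, at 1.68 and between 2.18 and 3.32. The differences between libraries of the same group were not tested. Between the groups, Cyp2a4, Ddx3y, Kdm5d, Eif2s3y and Uty did not pass (limma adjusted p = 0.0544, 0.329, 0.184, 0.673 and 0.272), while Gstm3 did (0.0223).

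A hypothesis for the fall of Pklr, Tkfc, Khk and Rgs16 is lower activity of ChREBP, a glucose-responsive transcription factor, in SG. Of 3 other targets, Arrdc4 fell by 0.95 on the log2 scale (limma adjusted p = 0.0035), while Gpd1 had a log2 fold change of -0.44 (0.224) and Txnip of 0.45 (0.354). Their median of -0.436 lay between the bound set for the hypothesis (-0.5) and the median of all genes (-0.135), so the test left it open, and it may hold for some targets only.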
